A study of Homo sapiens and Mus musculus with 7 samples.

How the data were processed

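Total RNA from 7 samples was hybridised to Affymetrix expression arrays, 5 human and 2 mouse. The deposited values are array intensities on a linear scale, made by the authors with MAS5 per the submitters' processing notes; the MAS5 version and settings are not given in the sources used here. The values show a 2% trimmed mean of 500.1 on each human array, so each array had been scaled as a whole before deposit. Array medians lay between 58.0 and 63.5 in the human table and between 75.4 and 80.1 in the mouse table. No detection calls were used, and the filter on low values rests on these medians. For arrays, their number limits the precision, and each of the 7 groups had 1 array.

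Human arrays held 54675 probe sets and mouse arrays 45101, of which 62 and 64 were control probe sets and were left out. Gene symbols came from the platform annotation. Of the human probe sets 41091 had 1 symbol, 1801 several and 11721 none, and of the mouse probe sets 34945, 932 and 9160. Human symbols were compared with a RefSeq gene table through the gene identifier (41037 matched, 0 updated), and mouse symbols are those of the annotation, which can be old. Probe sets with several symbols or none named no gene. Each gene was represented by its probe set with the highest mean signal, with probe sets marked as cross-hybridising (_x_at) used only where there was no other.

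Differences were computed as log2(signal + c), where c was the 25th percentile of a table, 12.6 in human and 20.5 in mouse. This scale understates the differences of dim genes. A gene was kept in a comparison when at least 1 compared array was above its own median, and called bright when at least 1 was above its 75th percentile. The comparisons were HeyA8 shRNA4 and HeyA8 shRNA6 against the HeyA8 pLKO control, HepG2 shRNA6 against the HepG2 pLKO control, and Fas knockout against wild-type mouse liver. With 1 array per group single comparisons were not tested, and their genes are counted by size, at least 2-fold.

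For the human arrays limma 3.58.1 in R 4.3.3 fitted the cell line and the knockdown together, with a trended prior variance, 2 residual degrees of freedom and Benjamini-Hochberg adjustment. A second fit with an interaction term tested the difference between HepG2 and HeyA8, with 1 residual degree of freedom. The fit of the common effect was tested on simulated data with 200 changed genes. Gene lists, 20 human and 37 mouse, were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and all alternatives but those said to be chosen after seeing the data. Human lists were tested in the common fit with camera in limma, at a preset correlation of 0.01 and with an estimated correlation, where camera uses the residual degrees of freedom in place of 13934. In single comparisons the median of a list was given as a percentile among 10000 random lists matched on mean expression, which describes these arrays only. The lists themselves were not altered, but a lookup of older gene symbols that had put 3 other genes in the place of listed ones (in the JNK, fatty acid and ribosomal lists) was corrected after results had been seen. List members that the annotation did not pair with a probe set of their own were left out. The overlap of the HeyA8 hairpins was set beside 100 simulations of unchanged arrays against a shared control, with noise drawn from the difference between the hairpin arrays. Genes shared between systems were set beside 1000 shuffles of the calls within 10 brightness bins of each comparison. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

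Named genes were chosen by a fixed rule. FAS, FASLG, FADD, CASP8, JUN, FOS, EGR1 and MYC were always named. For HeyA8 these were joined by the 10 higher and 10 lower bright genes with the largest smaller ratio of both hairpins, for HepG2 and mouse liver by the 12 bright genes with the largest ratio in each direction, and for the common effect, where no gene passed, by the 10 per direction with one sign in all 3 comparisons. At most 4 members were named per list and comparison, those with the largest ratio. Alternatives were other pseudocounts, quantile normalization, arrays scaled to equal medians, no filter and a stricter filter on low values, other rules for probe sets, other size thresholds, no variance trend, no cell line term, and leaving out each array in turn.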

Results

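Gene expression was measured on 7 Affymetrix arrays, each from the total RNA of 1 sample. The samples formed 3 systems with and without Fas (CD95), the cell surface receptor for Fas ligand that can start apoptosis. HeyA8, a human ovarian cancer cell line, was represented by 3 arrays: stable knockdown of FAS by the hairpin shRNA4, stable knockdown by the hairpin shRNA6, and a control carrying pLKO, a lentiviral vector used to express hairpins. HepG2, a human liver cancer cell line, was represented by 2 arrays, shRNA6 and the pLKO control. Liver tissue of male C57/BL6 mice aged 2 months was represented by 1 wild-type and 1 Fas knockout array. Each of the 7 groups held 1 array, so no difference within a single comparison has a replicate check, and the number of arrays limits the precision of every value. Where the human arrays are fitted together, p-values of single genes rest on the spread between these samples, which may be technical. They also draw on a prior variance pooled over all genes, with 5.78 degrees of freedom beside the 2 residual ones. The spread between samples is the difference between the HeyA8 hairpins and the difference of the knockdown effect between the cell lines, not a spread of replicates. In the fit of the difference between HepG2 and HeyA8 it is the hairpin difference alone, and HepG2 is taken to vary like HeyA8. List tests at a preset correlation instead compare listed genes with other genes, on 13934 degrees of freedom. Their p-values thus do not measure a spread between samples. The deposited signals had a 2% trimmed mean of 500.1 on each human array and nearly the same value on each mouse array. Differences are given as log2 ratios of signal plus a pseudocount, which understates the differences of dim genes.

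FAS itself was lower on every knockdown and knockout array than on its control. In HeyA8 the most intense FAS probe set gave a signal of 2104 in the control, 1184 with shRNA4 and 856 with shRNA6, log2 ratios of -0.82 and -1.29. In HepG2 the same probe set gave 1087 in the control and 631 with shRNA6, a log2 ratio of -0.77. Across the 4 FAS probe sets above the array median, the mean log2 ratio was -1.03 ± 0.18 (SD over 4 probe sets) for shRNA4 in HeyA8, -1.61 ± 0.29 for shRNA6 in HeyA8 and -0.92 ± 0.19 for shRNA6 in HepG2. Between 41.9% and 56.3% of the control signal was left with shRNA4, between 24.2% and 40.7% with shRNA6 in HeyA8 and between 44.5% and 58.1% in HepG2. Mouse Fas was measured by 1 probe set, at 560 in the wild-type liver and 169 in the knockout, 30.3% of the wild-type signal. Where that probe set lies relative to the altered part of the gene is not given in the sources used here.

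**Figure D1:**
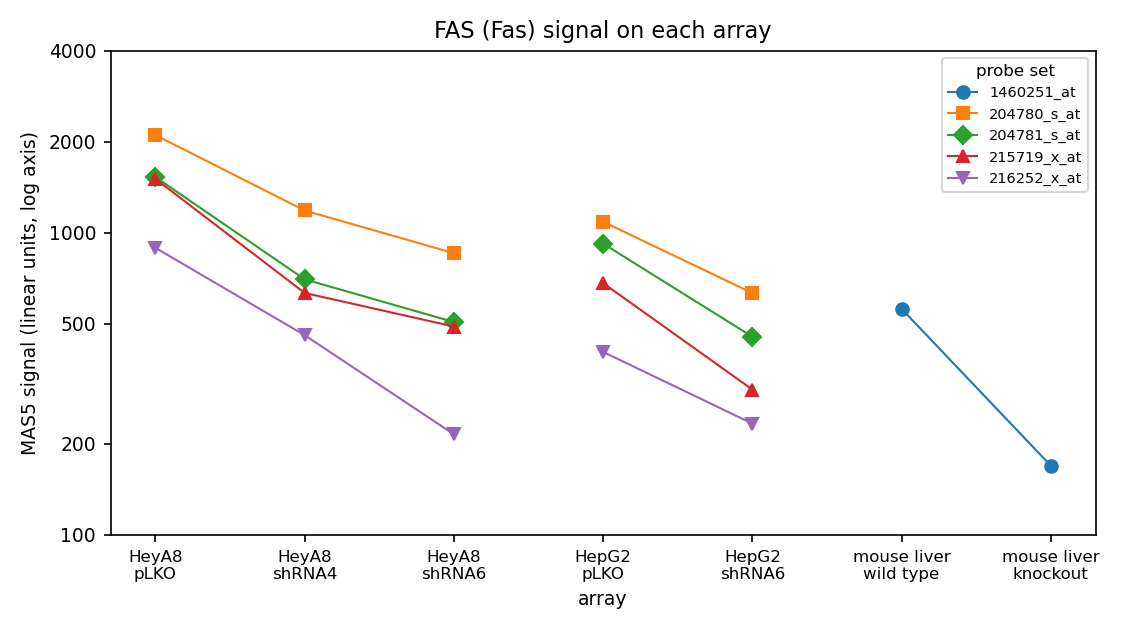
MAS5 signal of FAS (human) or Fas (mouse) on each of the 7 arrays, on a log axis, with 1 point per probe set and array and lines joining the arrays of one system. All 4 human probe sets sit below their control with each hairpin, and the mouse probe set lies at 560 in wild type and 169 in the knockout.

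Other parts of the Fas pathway were measured beside it. FADD, the adaptor that joins Fas to caspases, had log2 ratios of 0.15 and 0.13 with shRNA4 and shRNA6 in HeyA8, -0.13 in HepG2 and -0.13 in mouse liver, where its other kept probe set gave -1.06. CASP8, the initiator caspase of the pathway, had log2 ratios of -0.08, 0.04, 0.21 and -0.19 in the same order, and its other kept probe set gave 0.15, 0.21 and 0.51 in the human comparisons. FASLG, the ligand, was below the array median on all arrays, with signals of 30.4, 34.8 and 35.9 in HeyA8, 11.3 and 38.5 in HepG2 and 32.5 and 37.3 in mouse liver, and was left out. Of the other death receptor genes, TNFSF10, which encodes the ligand TRAIL, was higher in HepG2 at a log2 ratio of 1.55, and CFLAR, an inhibitor of caspase-8 activation, was at 0.20, -0.38 and 0.57 in the 3 human comparisons. Medians of the death receptor list were -0.01, -0.00 and 0.04 in the human comparisons and -0.03 in mouse liver. Scaling arrays to equal medians turned each of these signs, but relative to the median of all genes they were -0.03, -0.01, 0.05 and -0.02, and none turned under either other scaling.

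In HeyA8 cells the question was which genes stood apart from the control with both FAS hairpins. EGR1, an immediate-early zinc finger transcription factor, had the lowest log2 ratio of 7674 bright genes with shRNA4, where bright means a signal above the 75th percentile on at least 1 of the compared arrays. Its signal was 2661 in the control, 337 with shRNA4 and 906 with shRNA6, log2 ratios of -2.94 and -1.54, and its other probe sets gave -2.32 and -2.91 with shRNA4. FOS, a subunit of the AP-1 transcription factor, was at 1214 in the control, 214 with shRNA4 and 445 with shRNA6, log2 ratios of -2.44 and -1.42. JUN, its AP-1 partner, was not lower, with log2 ratios of 0.58 and 0.30, and one of its other probe sets gave -0.07 with shRNA6. MYC, a growth-promoting transcription factor, was at 0.33 and 0.19.

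Further bright genes lower with both hairpins included HEY1, a repressor induced by Notch (-1.37 and -1.24), MAML3, a coactivator of Notch (-1.05 and -1.14), and GREM1, a secreted antagonist of bone morphogenetic proteins (-1.06 and -1.21). ABI3BP, PNRC1, KLHL24, LRATD2 and DHRS3, a retinaldehyde reductase, completed the 10 lowest, with log2 ratios between -0.94 and -1.52. Bright genes higher with both hairpins had smaller differences. PIP5K1A, a phosphoinositide kinase, was at 1.41 and 1.18, although its other probe sets gave 0.34 and 0.15 with shRNA6. The insulin-like growth factor carriers IGFBP1 (0.93 and 1.06) and IGFBP3 (1.20 and 0.69) were higher, as were VANGL1, a planar polarity protein (1.13 and 0.91), and TULP3, which acts in transport into cilia (0.87 and 0.82). BLMH, SSBP4, ANKRD33B and the pseudogene AADACP1 lay between 0.64 and 0.74. The probe set annotated to the microRNA gene MIRLET7D was at 0.81 and 0.68. Other probe sets of VANGL1 gave 0.02, 0.45 and -0.07 with shRNA6, and those of SSBP4 gave 0.07 and -0.04.

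Interferon-stimulated genes were lower in HeyA8 with both hairpins. Of 16 kept members 13 were below 0 with shRNA4 and 16 with shRNA6, with list medians of -0.39 and -0.52, at percentiles 0.04 and 0 of 10000 random lists matched on expression. OAS2, an antiviral RNA-sensing enzyme, was at -1.24 and -2.34, and IFIT2, an interferon-induced RNA-binding protein, at -1.14 and -0.84. The ERK output list, made of genes induced by the ERK kinases and their feedback inhibitors, had medians of -0.40 and -0.16, with 13 and 14 of 18 members below 0. Beside EGR1, its largest differences with shRNA4 were in the feedback inhibitor SPRY2 (-0.80), IER3 (-0.76) and the ERK phosphatase DUSP6 (-0.60). Medians of the cholesterol synthesis list were -0.23 and -0.11, with 13 of 15 and 12 of 16 members below 0. HMGCS1, an early enzyme of that pathway, was at -0.39 and -0.50, and INSIG1, which holds back its regulator, at -0.70 and -0.66, but IDI1 was at 0.81 with shRNA4 and MVD at 2.02 with shRNA6. NF-kB targets and cytokines had medians of -0.14 and -0.28, with 14 of 19 members below 0 with each hairpin. The chemokine CCL20 was at -2.04 and -0.90 and PTGS2, the inducible cyclooxygenase, at -2.20 with shRNA4, but the chemokines CXCL3 (1.04), CXCL8 (0.89) and CXCL1 (0.79) were higher with shRNA6. The JNK pathway list had medians of -0.19 and -0.10, with 9 of 14 and 10 of 15 members below 0 and MAPK10 at -0.83 and -0.78.

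With both hairpins 72 genes were at least 2-fold higher and 84 at least 2-fold lower, of 11754 genes kept in both comparisons. With shRNA4 alone 289 genes were higher and 290 lower of 12175, and with shRNA6 alone 245 and 268 of 12152. Among the 7536 genes bright in both comparisons, 1 was higher (PIP5K1A) and 9 were lower. Both hairpins were set against the same control array, which could not be split. Simulated unchanged arrays against a shared control gave a mean of 56.2 genes higher in both (at most 80 in 100 simulations) and 157.9 lower in both (at most 187), while independent lists would share 1.02 and 6.61, from the 122 and 98 genes higher and 290 and 268 lower with shRNA4 and shRNA6 among the 11754. For bright genes the simulated means were 3.98 higher and 7.54 lower, and the independent values 0.0080 and 0.127. Across the 11754 genes the log2 ratios of the hairpins had a Pearson correlation of 0.55 (Spearman 0.47) beside 0.60 in the simulations (0.58 to 0.63), and a covariance of 0.0899 beside a simulated 0.116, a difference of -0.0261. The 72 shared higher genes lay above the simulated mean and below its highest value, the 84 shared lower genes below the simulated mean. The simulated noise came from the difference between the hairpin arrays. Real differences between the hairpins therefore count as noise and can raise the simulated counts. An effect of both hairpins and the shared control thus cannot be told apart by these overlaps.

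In HepG2 cells the question was which genes differed between shRNA6 and the control. SIRPA, an inhibitory receptor of the immunoglobulin family, was at 79.0 with shRNA6 and 613 in the control, a log2 ratio of -2.77, although its other probe set gave -0.82. COL1A1, a fibrillar collagen chain, was at -2.40, with other probe sets at -2.85 and 0.59. The long noncoding RNA LINC02381 had the lowest ratio, -4.30, with signals of 31.9 and 863. Lower too were ASB4 (-1.94), TACC1, a centrosome-associated protein (-1.53), CHST15, a sulfotransferase (-1.52), FOS (-1.41), the potassium channel KCNJ10 (-1.40) and SOCS2, a suppressor of cytokine signalling (-1.37). FADS3 (-1.63) and TGM2, a protein crosslinking enzyme (-1.46), had other probe sets at -0.11 and between -0.68 and -0.49, and PRIMA1, which anchors acetylcholinesterase, was at -1.41.

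Of the genes higher in HepG2 with shRNA6, the metalloprotease subunit MEP1A was at 754 against 26.1 in the control, a log2 ratio of 4.31. GSTA1, a glutathione transferase, was at 2.99 with another probe set at 0.17. CDO1, which oxidises cysteine, was at 2.31, BHMT, a homocysteine methyltransferase, at 2.03 and HAL, which breaks down histidine, at 1.61. The Wnt antagonist DKK4 (2.41), ENPP2, the enzyme autotaxin (1.81), TNNI2 (2.07), UNC93A (1.79), the manganese exporter SLC30A10 (1.43) and TMED6 (1.42) were also higher. All 3 probe sets of TNFSF10 were higher, at 1.55, 1.67 and 1.38. Other probe sets gave 1.07 for CDO1 and 0.48 for HAL.

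Among the lists in HepG2, immediate-early and AP-1 genes had a median of -0.30, with 17 of 19 members below 0 and a median lower than all 10000 random lists. JUNB, an AP-1 subunit, was at -1.67, KLF4 at -1.21 and EGR1 at -0.82, where the other EGR1 probe sets gave -0.34 and -1.30. JUN was at -0.30 and MYC at -0.10. Cholesterol synthesis genes had a median of 0.22, with 14 of 15 members above 0, among them LSS (0.48), SREBF2, the regulator of the pathway (0.38), and HMGCS1 (0.36). Interferon-stimulated genes had a median of 0.29, with 11 of 15 members above 0, led by IFIT1 (1.57) and OASL (0.89). That median was 0.10 both with no filter on low values and with arrays scaled to equal medians, and relative to the median of all genes it was 0.30, and 0.22 with equal medians. Mesenchymal and matrix genes had a median of -0.45 with 10 of 12 members below 0, including VIM, an intermediate filament (-1.37), but SNAI2, a mesenchymal transcription factor, was at 2.99. Ribosomal protein genes had a median of -0.14 with 18 of 19 members below 0, and a median of -0.03 after quantile normalization. Hepatocyte markers had a median of -0.05 with 12 of 18 members below 0, FGB, a fibrinogen chain, at 1.06, APOC3 at 0.75 and HPX at -0.60, and that median was 0.05 after quantile normalization. In all, 323 genes were at least 2-fold higher and 312 lower of 12167, and 29 and 40 of the 7775 bright genes. Scaling arrays to equal medians moved the median of all genes in this comparison by -0.11. Relative to the median of all genes, the cholesterol list median was 0.23 both before and after that scaling.

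The 3 knockdown arrays were then fitted together, with the cell line as a term, to find a common effect of FAS knockdown. The HepG2 array and a HeyA8 array among them carry the same hairpin, shRNA6. Of the genes lower in all 3 comparisons FOS had the largest smallest difference, at -2.44, -1.42 and -1.41. It had a common log2 effect of -1.70 ± 0.30 (SE, 5 arrays), lower in 3 of 3 comparisons, with an adjusted p of 0.991 by limma, and 5 genes had a lower common effect, PLSCR2 (-1.74), LINC02145 (-1.72), TEX22 (-1.71), L3MBTL4-AS1 (-1.71) and SLC19A3 (-1.71), the list being made after the values were seen. EGR1 had a common effect of -1.63 ± 0.43 (SE) and FAS of -0.93 ± 0.17 (SE), with the same adjusted p of 0.991. Other genes at least 2-fold lower in all 3 comparisons were PPL, a desmosome-associated plakin (between -2.15 and -1.20), PLSCR2 (-2.31, -1.89 and -1.26) and the antisense RNAs L3MBTL4-AS1 and TMEM202-AS1. PLSCR2 and both antisense RNAs were dim, with control signals between 59.6 and 79.7, near the control array medians of 61.1 in HeyA8 and 58.7 in HepG2. CEACAM5, a cell adhesion glycoprotein, was higher at 1.97, 1.84 and 1.27, and PLEKHN1 at 1.71, 1.93 and 1.31, each at signals of at most 139. THBS1, a matrix glycoprotein that binds collagen and integrins, was at -0.93, -1.29 and -1.13, and KLF9, a transcription factor, at -2.59, -1.24 and -0.97. Further genes with one sign in all 3 were DNAI1, WAS and HOXC5, lower, and LOC100506639, RAB4B, CNR2, SORCS2, MIR1915HG, NOVA2, EPN1 and PCSK4, higher, none of which passed the test. Each of these higher genes had a HeyA8 control signal below that array's median, from 6.44 (SORCS2) to 53.8 (EPN1). In HeyA8 they were thus kept through the knockdown arrays alone. HOXC5 was dim too, with control signals of 64.9 in HeyA8 and 65.7 in HepG2. Other probe sets turned the direction of NOVA2 and EPN1 in HeyA8.

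By limma, 0 of 13936 genes passed an adjusted p of 0.05 for the common effect, and 568 had an unadjusted p below 0.05. With no effect at all a share of 0.05 of the genes would fall there, which is more than 568. With arrays scaled to equal medians 2 genes passed, FOS and THBS1, each lower with an adjusted p of 0.0422. In that fit the variances were pooled more strongly over genes, with 14.3 prior degrees of freedom beside 5.78 without the scaling. For the difference of the knockdown effect between HepG2 and HeyA8, 0 genes passed and 613 had an unadjusted p below 0.05. That count too is smaller than a share of 0.05 of the genes. On simulated arrays of this design, with 13936 genes, the limma fit recovered 46% of 50 genes changed 2-fold. It recovered 72% of 50 changed 4-fold and 86% of 50 changed 8-fold, with 4 false calls. The simulated noise came from the difference between the HeyA8 hairpins, and a changed gene moved alike on every knockdown array. A difference of the effect between the cell lines was not simulated, so these rates can be too high for the real arrays.

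As a group, the immediate-early and AP-1 genes were lower in the common fit, though not evenly in HeyA8. There 12 of 20 members were below 0 with shRNA4 and 15 of 20 with shRNA6, and 3 were at least 2-fold lower with each. The list medians were -0.17 and -0.11, at percentiles 0.12 and 0.09 of the random lists. Of 20 tested members 17 had a common effect below 0 and 10 were lower in all 3 comparisons. Both HeyA8 comparisons share 1 control array, so such counts do not come from independent comparisons. The list had an adjusted p of 3.55e-07 by camera in limma at a preset correlation of 0.01. The call was lost with the correlation estimated from these arrays (adjusted p = 0.65 with an estimated correlation). That test differs in more than the correlation, which was estimated at 0.0155 for this list, since it uses the 2 residual degrees of freedom where the preset one uses 13934. No member passed among all genes, 3 passed when adjusted over the list alone, and 7 had an unadjusted p below 0.05. Beside FOS and EGR1, the nuclear receptor NR4A2 was at -1.82 with shRNA6 in HeyA8, and JUNB at -0.89, -0.58 and -1.67. Of the ERK output list, 15 of 18 members were below 0 and 8 were lower in all 3 comparisons, with an adjusted p of 1.97e-05 by camera (adjusted p = 0.83 with an estimated correlation), 0 members passing when adjusted over the list alone. For this list the correlation was estimated at 0.140, above the preset 0.01. The preset test thus takes its genes to be less correlated than they were on these arrays. The lists share EGR1, FOSL1 and IER3, and without those 3 genes the ERK output list had an adjusted p of 0.00154, an alternative chosen after seeing the data. SPRY1, another ERK feedback inhibitor, was at -0.52, -0.17 and -0.47 and PHLDA1 at -0.55, -0.14 and -0.26. None of the other 18 human lists passed, the lowest adjusted p being 0.129 for the unfolded protein and integrated stress response, in which DDIT4, an inhibitor of mTOR signalling, was at -1.48, -0.86 and -0.45. Both lists passed at the preset correlation without each of the 5 arrays in turn, although without either HepG2 array the knockdown effect rests on HeyA8 alone and without the HeyA8 control on 1 pair of HepG2 arrays. The number of lists passing was 4 without the HeyA8 shRNA4 array, 3 without the HeyA8 shRNA6 array, 4 without the HeyA8 control and 9 without either HepG2 array.

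**Figure D2:**
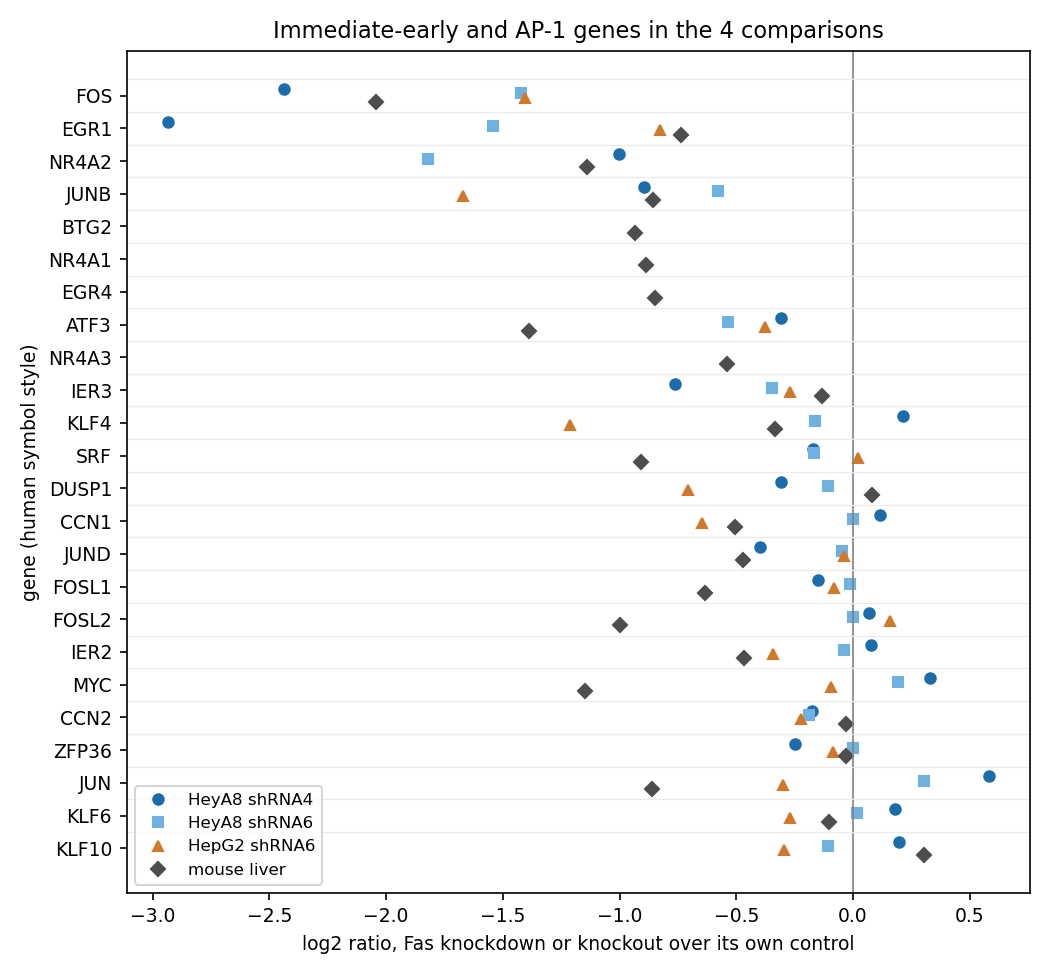
Log2 ratio of each kept immediate-early or AP-1 gene (24 genes) in the 4 comparisons of Fas knockdown or knockout with control, with 1 symbol per comparison and no error bars because each group holds 1 array. FOS lies at or below -1.41 and EGR1 at or below -0.74 in all 4 comparisons, while JUN lies at 0.58 and 0.30 in HeyA8 and at -0.86 in mouse liver.

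In mouse liver the question was which genes differed between the Fas knockout and the wild-type animal. Fos was at 3068 in wild type and 729 in the knockout, a log2 ratio of -2.04, the lowest but 4 of 7065 bright genes. Most of the immediate-early list went with it: 22 of 24 kept members, Fos included, were below 0. The list median was -0.69 and it was lower than all 10000 random lists. Atf3, a stress-induced transcription factor, was at -1.39, Myc at -1.15 and Nr4a2 at -1.14. Jun was at -0.86, with another probe set at -0.88, and Egr1 at -0.74. The ERK output list had a median of -0.44 with 11 of 15 members below 0, led by Dusp6 (-0.79), Egr1, Fosl1 (-0.63) and Epha4 (-0.63).

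Lists of immune signalling were lower in the knockout liver as well. Interferon-stimulated genes had a median of -0.36, with 19 of 24 members below 0 and Oas2 at -2.18, Ifit2 at -0.86 and Stat2, a mediator of interferon signalling, at -0.81. NF-kB targets and cytokines had a median of -0.35 with 11 of 13 members below 0, including the cytokine Lif (-1.66), the NF-kB subunit Relb (-1.23) and the chemokine Ccl2 (-1.15). Acute phase genes had a median of -0.11 with 15 of 20 below 0, and p53 targets a median of -0.25 with 14 of 16 below 0. Markers of other liver cells also had medians below 0: -0.56 for neutrophils, -0.38 for MHC class II genes, -0.14 for macrophages and Kupffer cells, -0.24 for sinusoidal endothelium, -0.28 for T cells (4 genes, percentile 19.2), -0.41 for B and plasma cells (5 genes, percentile 8.25) and -0.16 for stellate cells. Hepatocyte secreted proteins had a median of 0.02.

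Genes of lipid and foreign compound metabolism were slightly higher in the knockout liver. All 14 fatty acid synthesis genes were above 0, with a median of 0.20, at percentile 99.97 of 10000 random lists, and with Fasn, the fatty acid synthase, at 0.56, Me1 at 0.39 and Elovl5 at 0.38. Xenobiotic metabolism genes had a median of 0.17 with 14 of 16 above 0, led by the glutathione transferase Gsta2 (0.67) and the cytochromes Cyp3a13 (0.64) and Cyp2c55 (0.55). Cholesterol synthesis genes had a median of 0.12 with 14 of 17 above 0, among them Insig1 (0.43) and Hmgcs1 (0.38), and a median of 0.07 after quantile normalization.

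Outside these lists, the lowest bright genes were Adi1, an enzyme of methionine salvage (3946 in wild type and 194 in the knockout, a log2 ratio of -4.21), Abhd1 (-3.33), Slc10a2, a bile acid transporter (-2.88), and Pik3ap1, a signalling adaptor of immune cells (-2.85). Il6st, the shared receptor subunit of interleukin-6 family cytokines, was at -1.95, and Bmf, a pro-apoptotic BCL2 family member, at -1.51. Them7 (-1.77), the interferon-inducible gene Ifi202b (-1.64), Hddc3 (-1.57) and Nnt, a mitochondrial transhydrogenase (-1.46), were lower too. Highest was Mndal, of the same interferon-inducible family as Ifi202b (22.7 and 681, a log2 ratio of 4.02), followed by Tmem87a (2.10), Tufm, a mitochondrial translation factor (1.99), Exd1 (1.85), C730036E19Rik (1.68) and Robo1, an axon guidance receptor (1.53). The lipid genes Pctp, a phosphatidylcholine carrier (1.47), and Elovl3, a fatty acid elongase (1.42), were higher, as was Ppp1r3c, which targets a phosphatase to glycogen (1.35). Zfp874a, Lrrc61 and Dct lay between 1.23 and 1.38. Other probe sets disagreed for 6 of the 9 genes that had one: Adi1 gave -0.16 and -2.25, Pik3ap1 0.08, Il6st between 0.15 and 1.14, Bmf 1.03 and Tufm 0.18, and 1 of those of Nnt had the opposite sign. In all, 213 genes were at least 2-fold higher and 310 lower of 12047, and 18 and 26 of the 7065 bright genes.

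Across systems, correlations over genes were near 0. Log2 ratios in HepG2 had Pearson correlations of 0.01 with shRNA4 in HeyA8 and 0.04 with shRNA6 in HeyA8, over 10610 and 10597 genes. With the stricter filter they were -0.0202 and 0.159. Mouse liver, matched by gene symbol, had correlations of 0.02, 0.04 and 0.04 with the 3 human comparisons over 8396 to 8401 genes. Genes are not independent replicates, so no p is given. HepG2 shared 12 higher and 12 lower genes at least 2-fold apart with shRNA4 in HeyA8 and 8 and 17 with shRNA6 in HeyA8, and mouse liver shared 5 and 3, 2 and 8, and 2 and 8 with shRNA4, shRNA6 and HepG2. In 1000 shuffles of the calls among genes of like brightness in both comparisons, added after seeing the data, the means were 10.3 and 8.05, 7.93 and 7.67, 3.61 and 4.17, 2.70 and 4.17, and 2.72 and 5.84 in the same order. The 17 genes lower with shRNA6 in both human lines lay above the highest shuffled count, 15, and each of the other counts was within the shuffled range. Both arrays of that pair carry the same hairpin, so the overlap cannot tell an effect of shRNA6 itself from one of FAS loss. These shuffles describe these arrays only. With the weakest FOS ratio, -1.41, as the limit, FOS was the 1 gene of 7738 kept in all 4 comparisons at or below it in each. Among the 16 lists measured in both species, the immediate-early and AP-1 list, the ERK output list and the NF-kB list had medians below 0 in all 4 comparisons under each scaling tried. So did the unfolded protein list relative to the median of all genes, at -0.05, -0.08, -0.03 and -0.06. The NF-kB medians were -0.14, -0.28, -0.02 and -0.35, and that in HepG2 lay at percentile 43.6 of the random lists.

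**Figure D3:**
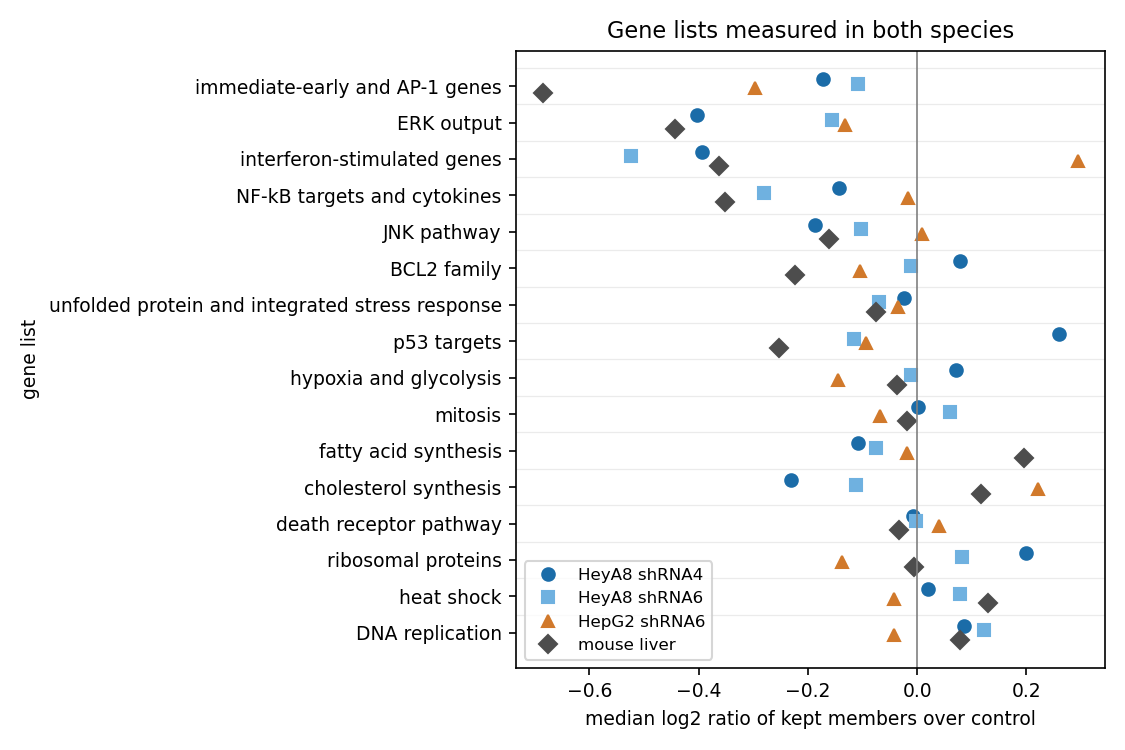
Median log2 ratio of the kept members of 16 gene lists in the 4 comparisons of Fas knockdown or knockout with control, with 1 symbol per comparison. The immediate-early medians are -0.17, -0.11, -0.30 and -0.69, and the interferon-stimulated medians -0.39, -0.52, 0.29 and -0.36, in the order HeyA8 shRNA4, HeyA8 shRNA6, HepG2 and mouse liver.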

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

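The test of an interferon response to the hairpin RNA and the list tests of the difference between cell lines, under each scaling, were chosen after the results were seen. Interferon-stimulated genes had a median log2 ratio of 0.29 in HepG2 with shRNA6, against -0.39 and -0.52 in HeyA8 with shRNA4 and shRNA6, opposite directions in the cell lines. Partly different genes were kept in each line: over the 10 kept in all 3 comparisons the medians were 0.11 in HepG2, with 4 of 10 below 0, and -0.41 and -0.52 in HeyA8, and the 0.29 was 0.10 with no filter or equal medians (relative to the median of all genes, 0.30 and with equal medians 0.22). The difference itself, HepG2 minus HeyA8, had an adjusted p of 3.22e-04 over 21 genes by camera in limma at the preset correlation (adjusted p = 0.652 with an estimated correlation, a test on 1 residual degree of freedom), and of 0.00320 after quantile normalization. Whether hairpin RNA itself gave an interferon response stays open: the higher of the HeyA8 medians was -0.39, but the insert of the control vector is not given in the sources used here. The shared HeyA8 control array may be the source of the lower values there. The mean product of both hairpins' log2 ratios over the list was 0.424, above the 0.143 for simulated unchanged arrays. Those simulations draw noise gene by gene, so they cannot represent a control array in which these genes deviate together. Without another control array the control and the knockdown cannot be told apart. An effect of FAS loss that depends on the cell line also stays open, untested.

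Cholesterol synthesis genes likewise had opposite directions, with a median of 0.22 in HepG2 and -0.23 and -0.11 in HeyA8, and the difference had an adjusted p of 2.27e-06 by camera (adjusted p = 0.652 with an estimated correlation). By the same test ribosomal protein genes (3.63e-07, lower in HepG2) and fatty acid synthesis genes (0.0204, higher in HepG2 than in HeyA8) differed at the preset correlation only (adjusted p = 0.652 with an estimated correlation for each). The estimated correlation was 0.602 for the ribosomal list, 0.0833 for the cholesterol list and -0.0606 for the fatty acid list. Fatty acid medians were -0.11 with shRNA4, -0.07 with shRNA6 and -0.02 in HepG2, where 8 of 11 members were below 0. After quantile normalization the ribosomal difference was lost (adjusted p = 0.766), with medians relative to all genes of -0.0001, -0.03 and -0.02 in the order shRNA4, shRNA6 and HepG2, and the cholesterol (1.99e-07) and fatty acid (0.00320) differences still passed.

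Probe sets with no symbol or several, 13522 in human and 10092 in mouse, entered no comparison of genes, and some bright ones differed from control: 3, 1, 6 and 7 were at least 2-fold higher and 17, 4, 4 and 11 lower in HeyA8 with shRNA4, HeyA8 with shRNA6, HepG2 and mouse liver. The highest in HeyA8 had a log2 ratio of 1.20 with shRNA4 (signals of 1741 and 753) and 1.18 with shRNA6 (421 and 179). The highest in HepG2 was at 1.93 (464 and 112), and the highest in the knockout mouse liver at 3.68 (641 and 31.0). The lowest were at -1.60, -1.44, -1.53 and -1.85 in the same order.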

How the results depend on the processing

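Of 167 alternative values of the main results 123 stayed within their limits, 43 moved and 1 became stronger, and of 1419 for single genes and lists 1362 stayed, 38 moved, 12 became weaker and 7 reversed. Counts of genes at least 2-fold apart depended most on the treatment of dim genes. Higher and lower counts with both HeyA8 hairpins were 8 and 11 with the table's median as pseudocount, 361 and 337 with no filter, 1 and 9 with the stricter filter, 184 and 303 at 1.5-fold, 28 and 24 at 3-fold, and 245 to 289 and 268 to 290 with 1 hairpin left out. In HepG2 they were 94 and 81, 1284 and 971, 29 and 40, 788 and 749, and 147 and 124 under the same settings but the last. In mouse liver they were 41 and 97, 690 and 865, 18 and 26, 589 and 919, and 71 and 126. A larger pseudocount shrinks ratios, a filter changes the genes counted and another threshold the size asked for, so these shifts follow from the construction. The common effect gave 2 genes by limma with equal medians and 0 under the other settings, leaving out each array included, where 43 to 847 genes had an unadjusted p below 0.05; the cause was not tested. Those unadjusted counts lie near or below the share of 0.05 of the fitted genes that no effect would give. With equal medians the prior variance of the common fit had 14.3 degrees of freedom, beside 5.78 in the main setting. Mouse Fas was at -1.37 with the median pseudocount. With the stricter filter the correlation across genes of HepG2 was 0.159 with HeyA8 shRNA6 and -0.0202 with HeyA8 shRNA4, and the cause was not tested. The number of human lists passing was 0 with an estimated correlation, where camera uses 2 residual degrees of freedom in place of 13934 and each list's own correlation in place of 0.01. It was 3 without HeyA8 shRNA6 and 4 without HeyA8 shRNA4, and the cause was not tested. Without the HeyA8 control the knockdown effect rests on HepG2 alone, and without either HepG2 array on the same HeyA8 comparison. Of list differences between the lines, tests chosen after seeing the data, 4 passed, 0 with an estimated correlation, 3 after quantile normalization and 9 with equal medians; the cause was not tested. With equal medians, chosen for lists after seeing the data, the median of the unfolded protein list in HeyA8 with shRNA6 reversed to 0.0039 and that of male-biased genes in mouse liver to 0.03, as that scaling shifts all genes upward there; relative to the median of all genes they were -0.08 and -0.04 under it. Without _x_at and _s_at probe sets, Bmf was at 1.03 in mouse liver and NOVA2 at -0.29 and below -1 (-1.0014) in HeyA8, and as a mean over probe sets EPN1 was at -0.50 and -0.39, other probe sets being read in each case. Signal over background limits dim genes most: FOS, a bright gene, stayed at or below -1.35 under both other scalings.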

Other observations

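Tests of immune cell content and of array scaling were chosen after the results were seen. In the knockout mouse liver, genes of the circadian clock had a median log2 ratio of -0.28 with 14 of 16 members below 0, lower than all 10000 random lists, although Nr1d1, a repressor within the clock, was at 1.38. Cry1 and Cry2, which encode clock repressors, were both at -0.67. Sinusoidal endothelial markers were led by Lyve1 (-0.45) and Pecam1 (-0.41), and neutrophil markers by Csf3r (-1.67). Cholangiocyte markers went both ways, with Sox9 at -2.44 and Krt7 at 1.69 (median -1.08 over 4 genes), and 3 erythroid markers had a median of 0.48. NK cell markers (-0.09), bile acid genes (0.06), PPAR-alpha targets (0.10), female-biased genes (0.05), DNA replication genes (0.08) and heat shock genes (0.13) had smaller medians. Male-biased genes (-0.06), the unfolded protein response (-0.07), hypoxia genes (-0.04), muscle and adipose markers (-0.07) and pancreatic markers (-0.0033) changed sign under another scaling but not relative to the median of all genes. Mitosis genes (-0.02), ribosomal proteins (-0.0060) and gluconeogenesis genes (0.0050) changed sign relative to all genes too, and hepatocyte secreted proteins (0.02) only relative to them. JNK pathway genes had a median of -0.16 and BCL2 family genes of -0.22.

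In the human lines p53 targets were at 0.26 with shRNA4 in HeyA8, with 12 of 16 members above 0 and CDKN1A, a cell cycle inhibitor, at 0.38, but at -0.12 with shRNA6 and -0.09 in HepG2. Mesenchymal genes also differed between the HeyA8 hairpins, at 0.22 and -0.22, although THBS1 was lower with both. DNA replication genes were at 0.09, 0.12 and -0.04, with the cyclin CCNE2 at 0.34, 0.33 and 0.32. Medians for shRNA4, shRNA6 and HepG2 were 0.08, -0.01 and -0.10 for the BCL2 family, 0.0017, 0.06 and -0.07 for mitosis, -0.02, -0.07 and -0.04 for the unfolded protein response, 0.02, 0.08 and -0.04 for heat shock, -0.11, -0.07 and -0.02 for fatty acid synthesis and 0.07, -0.01 and -0.14 for hypoxia. They were -0.22, 0.07 and -0.06 for epithelial genes, 0.26, 0.03 and -0.12 for the small RNA machinery and 0.20, 0.08 and -0.14 for ribosomal proteins. Hepatocyte markers had medians of 0.41 and 0.54 over 4 and 3 genes in HeyA8, partly different ones. The filter can keep a gene through the knockdown array alone, and over the 2 markers kept in all 3 comparisons these medians were -0.03 and 0.31. JNK pathway genes were at 0.0090 in HepG2. Relative to the median of all genes, BCL2, mitosis, epithelial and ribosomal medians with shRNA6, hypoxia and ribosomal medians with shRNA4, and heat shock and hepatocyte medians in HepG2 changed sign under another scaling. Unfolded protein, fatty acid and hypoxia medians with shRNA6, and JNK medians in HepG2, did so only before the median of all genes was taken off.

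FOS was lower in all 4 comparisons. Array scaling does not account for it, since the weakest FOS log2 ratio under both other scalings was -1.35. Chance overlap is made less likely by 1000 shuffles of gene labels within brightness bins, with both HeyA8 comparisons kept together: a gene at or below the weakest FOS ratio in all 4 comparisons occurred in 1 of them (mean 0.001), though FOS itself set that limit, so the data hold at least 1, and genes of like brightness are taken to vary alike. RNA quality is argued against by the ratios of 3' to 5' signal of GAPDH and beta-actin, which differed between paired arrays by at most 1.12-fold. FOS and other immediate-early genes respond within minutes to serum, handling and stress, so a difference in harvest could give the same pattern, and it stays open beside an effect of Fas loss, both untested.

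The largest differences between the mouse livers may partly come from sequence differences under single probe sets. Of the named genes with another kept probe set, 66.67% (6 of 9) had one that gave under 50% of the ratio or the opposite sign, beside 41.67% (10 of 24) in the human lines (p = 0.259, 2-sided Fisher's exact test), so the explanation cannot be told apart from a difference in expression with so few genes. More or fewer immune cells stay open too: 1 of 5 immune lists had a median beyond 0.5 in size, but all 5 medians were below 0 and 1 list alone, that of macrophages and Kupffer cells, stayed short of 0.5 by more than the SD of its members. Nnt is known to be partly deleted in a C57BL/6 substrain. A difference in genetic background between the animals stays open, untested, for Nnt and for other large differences such as those of Mndal and Ifi202b.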
